A study of Homo sapiens with 40 samples.

How the data were processed

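Milk was sampled from 5 lactating donors at 8 clock times, every 3 h over 24 h, and each of the 40 samples was hybridised to 1 Illumina BeadChip array. Per the labels, RNA was taken from the milk fat globules, which carry some cytoplasm of the secreting mammary epithelial cell, with Trizol, and was amplified by in vitro transcription into biotin-labelled cRNA. Donors stand as the letters A to E, given in an arbitrary order. The labels carry the code GH0 without giving its meaning, and the samples were treated as a single untreated group. The labels do not state the order of collection. It was read from the sample numbers as 11AM first and 8AM last, and the linear term for collection time rests on it.

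Per the file headers, the deposited table without normalization holds, for each array and each of 22184 probes, the mean bead signal intensity, the number of beads, the standard error over beads and a detection p-value. The detection p-value compares a probe with the negative controls of its array. A second table deposited by the authors holds processed signal intensities. How the authors normalized these was not given in the sources used here. Their values were on a linear scale with column medians from 83.595 to 83.606 and none below 0. Each array's values followed the rank order of its raw signals, and sorted values differed between arrays by a median of 0.152% of their mean and by up to 62.1% among values above the median. They were used as an alternative only.

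Raw signal intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, which takes the negative control distribution from the detection p-values, adds an offset of 16 and takes log2. A probe was kept when its detection p-value was under 0.01 on at least 8 of the 40 arrays, which left 9967 probes. Gene symbols came from the platform annotation through the Entrez gene table, where 0 symbols needed an update. Of all probes 19715 had a single symbol and 2469 had none. The kept probes stood for 8568 genes, 763 of them had no symbol, and 576 genes had more than 1 kept probe. A gene's values are those of its brightest kept probe. Counts over probes use every kept probe. The files name no genome build and no position is given for any gene.

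Each probe was fitted in limma with donor as a fixed block, which pairs the arrays of a donor. The 24 h rhythm was tested by the moderated F of a cosine and a sine term with a 24 h period, and amplitude (peak to mean, log2) and peak hour (24 h clock) were taken from these terms. Other tests were any difference among the 8 clock times, differences among donors, and the interaction of donor with the 24 h terms. Contrasts were taken of night (11PM, 2AM and 5AM) minus day (11AM, 2PM and 5PM), and of evening (5PM, 8PM and 11PM) minus morning (5AM, 8AM and 11AM). P-values were adjusted by Benjamini and Hochberg over the kept probes of each test, all tests were two-sided, and a probe or gene counts as called at an adjusted p under 0.05. Errors of amplitudes and peak hours are the fit's SE. It comes from the scatter of all arrays of the 5 donors around a common curve. It does not measure how far donors differed in rhythm. Errors of contrasts are the SD of the 5 donors' own differences. The p-values of contrasts come from the fit's error over all arrays and not from this SD. A contrast can thus have a small adjusted p where donors differed widely. A test on the 5 donors' differences alone was not run. The number of arrays limits the precision of every value. Each clock time was sampled in a single day and each donor gave 1 array per clock time, so a repeat of the rhythm over a second day could not be tested.

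Fixed gene lists, 24 in all, were tested. They covered milk proteins and fat globule membrane, fatty acid and triglyceride synthesis, cholesterol synthesis, lactose synthesis and glucose handling, circadian clock, prolactin, growth hormone and insulin signalling, glucocorticoid responsive genes, immediate early genes, heat shock and cytosolic chaperones, endoplasmic reticulum and secretion, mineral and amino acid transport, proteasome and ubiquitin, cell cycle and mitosis, cytosolic ribosomal proteins and oxidative phosphorylation. The others held markers of luminal epithelial, myoepithelial and basal, monocyte and macrophage, neutrophil, lymphocyte, fibroblast, endothelial, adipocyte and red blood cells. Lists with at least 3 kept genes were tested in both contrasts with camera at a preset correlation of 0.01, adjusted over all lists and both contrasts, and again with an estimated correlation. Where a list is given below with an adjusted p for its direction, that p is camera's. A list's called genes were also counted with p-values adjusted over the list alone. Fry tested whether a list's genes moved, on balance, 1 way or in either direction. Fisher's exact test compared the share of genes with a 24 h rhythm inside and outside each list and was adjusted over the lists. It takes genes as independent, so its p can be too small where the genes of a list vary together.

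Genes are named by a fixed rule. It takes every tested circadian clock gene, CSN1S1, CSN2, CSN3, LALBA, LTF, XDH, BTN1A1, PLIN2, FASN, SREBF1, PRLR, STAT5A and ELF5, the 15 called genes with the largest amplitude, up to 4 called genes of each list with the largest amplitude, and the 10 highest and 10 lowest called genes of each contrast with the same sign in all donors. XIST, Y-linked genes, HLA genes and genes with common deletions or large genotype effects were left out, as was any gene as different between donors. A gene named outside the rule is said to be chosen after its values were seen. Samples, comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except for Fisher's exact test, the linear term for collection time, the covariate for probes detected and the fits without the array with the fewest probes detected, which were added afterwards.

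The alternatives were no background correction, scaling each array to its 75th percentile, the authors' processed values, no filter, a filter on detection on all 40 arrays, no donor block, a random donor effect, array weights, a trended and robust variance prior, a 12 h harmonic, each donor or clock time left out in turn, the mean over a gene's probes, other list tests and a detection threshold of 0.05. A block for the physical BeadChip was not run, because the files do not say which arrays shared a chip.

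In a check of the donor labels by expression profile, 39 of the 40 arrays correlated best with an array of the same donor after removal of the clock time means, and no pair of arrays had identical signals. If the arrays of a donor shared a chip, this could also raise their correlation. The fit was tested on simulated data with 9967 probes and the same 40 arrays. It called 86 of 100 probes given an amplitude of 0.25, 50 of 50 given 0.5 and 50 of 50 given 1, with 10 calls among the probes given none. The simulated noise was independent between probes and arrays. The 10 calls therefore do not show the error rate where probes share noise. The median error of the peak hour was 0.437 h at an amplitude of 0.25. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.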

Results

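The data were 40 arrays of RNA from milk fat globules. They came from 5 donors at 8 clock times, with 1 array for each donor and time. The arrays detected between 7796 and 10059 probes (median 9206), with median signals from 59.0 to 111. Of the 16578 genes with a probe, 6351 were detected on every array and 9570 on at least 1. Transcripts of the secreting epithelium were there throughout. Detected on all 40 arrays were 25 of the 28 milk protein and fat globule membrane genes, 18 of the 19 cholesterol synthesis genes and 27 of the 28 proteasome genes. CSN3, LALBA, FASN and CSN1S1 were among the brightest probes, with median ranks of 1, 2, 7 and 8. Many markers of other cell types gave no signal above background. All 9 red blood cell markers with a probe were detected on no array. So were 11 of 13 fibroblast, 16 of 20 lymphocyte, 8 of 12 endothelial, 8 of 16 neutrophil, 6 of 11 adipocyte, 7 of 12 myoepithelial and basal and 2 of 18 monocyte and macrophage markers. The number of probes detected did not differ detectably among clock times (permutation test within donors, two-sided, p = 0.72). Its mean was lowest at 11PM with 8904 ± 685 (SD, n = 5) and highest at 2PM with 9269 ± 386 (SD, n = 5).

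The first comparison asked which transcripts of the lactating mammary epithelium followed a 24 h course. Core clock genes were among those with the largest daily change. PER2 (probe ILMN_1738095), a repressor in the clock's feedback loop, peaked at 13.6 h with an amplitude of 1.03 ± 0.09 (SE of the fit). Its change from trough to peak was 4.19-fold (adjusted p = 6.8e-10). CRY2, which encodes another repressor, peaked at 14.3 h with an amplitude of 0.74 ± 0.05 (adjusted p = 8.1e-14). CRY1 peaked later, at 18.1 h, with 0.55 ± 0.06 (adjusted p = 7.6e-08). The activators BMAL1 and NPAS2 peaked on the other side of the day. BMAL1 peaked at 22.9 h with 0.31 ± 0.07 (adjusted p = 0.0051), and NPAS2 at 0.48 h with 0.37 ± 0.05 (adjusted p = 4.4e-06). BMAL1 was not called without donor D or without the donor block (adjusted p = 0.063 and 0.093).

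Other clock genes filled in the sequence of peaks. NR1D2, which encodes the nuclear receptor REV-ERB beta, peaked at 8.71 ± 0.26 h. The output transcription factor genes TEF and DBP peaked at 11.8 ± 0.31 h and 13.3 ± 0.45 h. BHLHE40, which encodes a repressor of clock-driven transcription, peaked at 14.3 ± 0.40 h, the kinase gene CSNK1E at 10.98 ± 0.74 h and NFIL3 at 19.2 ± 0.88 h. Of the 16 clock genes tested, 12 had a 24 h rhythm, and 12 also when adjusted over the list alone. This was a larger share than among other genes (Fisher's exact test, adjusted p = 0.0030). The kinase gene CSNK1D had an amplitude of 0.11 ± 0.03 with a peak at 9.74 h, while another probe of that gene peaked at 1.71 h without a call (adjusted p = 0.064). The call of CSNK1D ended without donor A, B, D or E, without 2PM, 5PM, 11PM, 2AM or 8AM and without the donor block (adjusted p from 0.054 to 0.32). CLOCK (0.26 ± 0.13, adjusted p = 0.23, and 0.029 without 2AM), HLF (0.10 ± 0.04, adjusted p = 0.10), TIMELESS (0.09 ± 0.06, adjusted p = 0.42) and RORA (0.04 ± 0.04, adjusted p = 0.67) were not called. NFIL3 was not called without donor D, without 8AM or without the donor block (adjusted p = 0.070, 0.099 and 0.051). NR1D2 was not above background on any array from 5PM to 2AM, TEF on any from 11PM to 5AM and DBP on any at 2AM, so their low points were not measured.

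**Figure D1:**
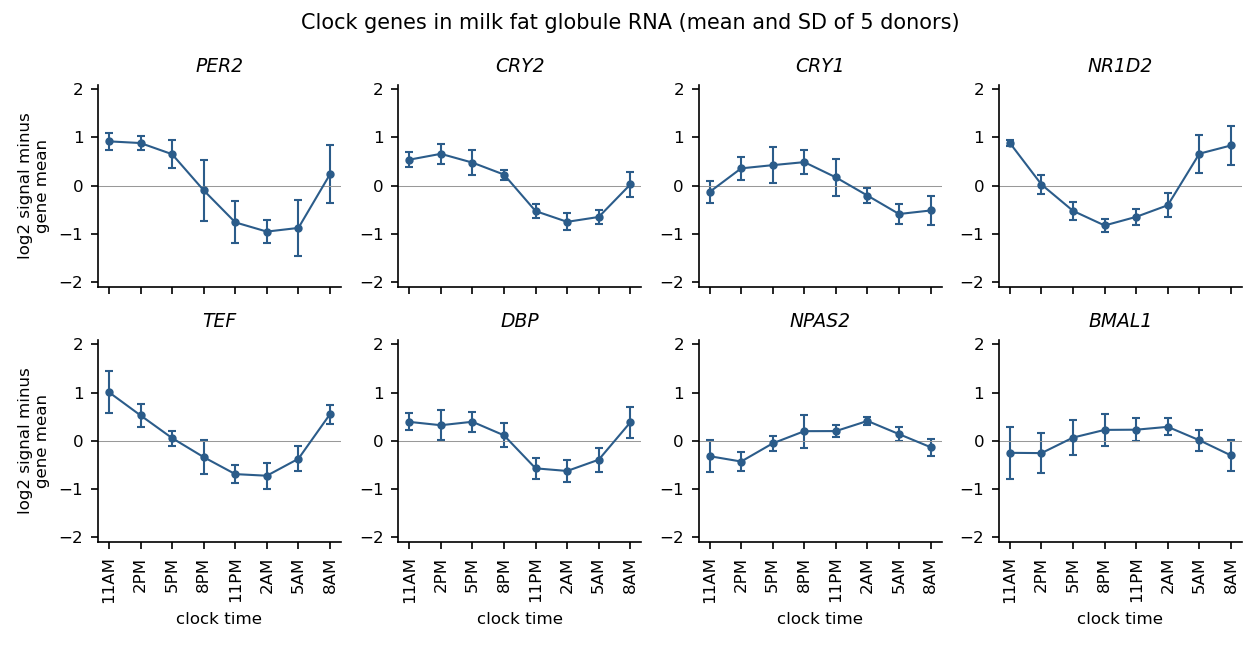
Log2 signal of circadian clock genes minus each gene's mean (vertical axis) against clock time (horizontal axis), with points for the mean of 5 donors joined by lines and bars for the SD of the donors after each donor's own mean was removed. PER2 and CRY2 peaked in the early afternoon (13.6 h and 14.3 h), and BMAL1 and NPAS2 around midnight (22.9 h and 0.48 h).

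Several genes that respond to glucocorticoid hormones also had large amplitudes. HSD11B2 (probe ILMN_1813350), whose enzyme converts cortisol into inactive cortisone, had the largest amplitude of the named genes, 1.28 ± 0.11 (SE of the fit). Its peak was at 13.6 h (adjusted p = 6.0e-10). It was above background on only 5 of 15 night arrays, so its low point was not well measured. FKBP5, a co-chaperone of the glucocorticoid receptor, peaked at 12.2 h (0.74 ± 0.07), the transcription factor gene ZBTB16 at 12.1 h (0.77 ± 0.10) and the kinase gene SGK1 at 11.05 h (0.57 ± 0.08). In this list 13 of 16 genes were rhythmic, and 13 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00060). That test takes genes as independent, while the correlation estimated between the genes of this list was 0.27.

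Several epithelial genes also followed the day. The keratin gene KRT7 had an amplitude of 0.81 ± 0.07 and peaked at 15.5 h, and the tight junction gene CLDN3 had 0.53 ± 0.05 at 14.3 h. The glutamate transporter gene SLC1A3 had 0.86 ± 0.07 at 14.4 h, and VTCN1, which encodes a surface protein of the B7 family, had 0.80 ± 0.08 at 15.1 h. Of the luminal epithelial markers 9 of 16 were rhythmic (9 adjusted over the list alone), and of the myoepithelial and basal markers 3 of 5 (4 adjusted over the list alone). Neither share differed from that of other genes (Fisher's exact test, adjusted p = 0.20 and 0.40).

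Transcripts of the major milk proteins gave no call. The casein genes CSN1S1, CSN2 and CSN3 had amplitudes of 0.03 ± 0.02, 0.03 ± 0.03 and 0.01 ± 0.02 (adjusted p = 0.40, 0.73 and 0.85). LALBA, whose product alpha-lactalbumin is part of lactose synthase, had 0.03 ± 0.02 (adjusted p = 0.58). XDH (0.02 ± 0.02), BTN1A1 (0.07 ± 0.04), STAT5A (0.03 ± 0.04) and FASN (0.0013 ± 0.022) were not called either. CSN3, LALBA, FASN and CSN1S1 lie near the top of the signal range. Scaled to the 75th percentile the amplitudes of CSN1S1, CSN2, CSN3 and LALBA were 0.09, 0.08, 0.05 and 0.08, and those of XDH, BTN1A1 and FASN 0.06 ± 0.04, 0.04 ± 0.04 and 0.06 ± 0.05, still without a call. Other milk genes were called. LTF, which encodes lactoferrin, peaked at 1.29 h (0.31 ± 0.08, adjusted p = 0.0075). The vitamin B12 binder gene TCN1 peaked at 13.8 h (0.21 ± 0.03), the complement inhibitor gene CD59 at 16.4 h (0.45 ± 0.06) and the lipid droplet gene PLIN2 at 12.1 h (0.13 ± 0.03). TCN1 and CD59 lost their calls in 2 of 26 alternatives each and PLIN2 in 1. LTF lost its call without donor E, without 2PM, without the donor block and with a linear term for collection time (adjusted p = 0.098, 0.061, 0.32 and 0.19). In all 7 of 25 milk protein and fat globule membrane genes were rhythmic, and 7 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.91).

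**Figure D2:**
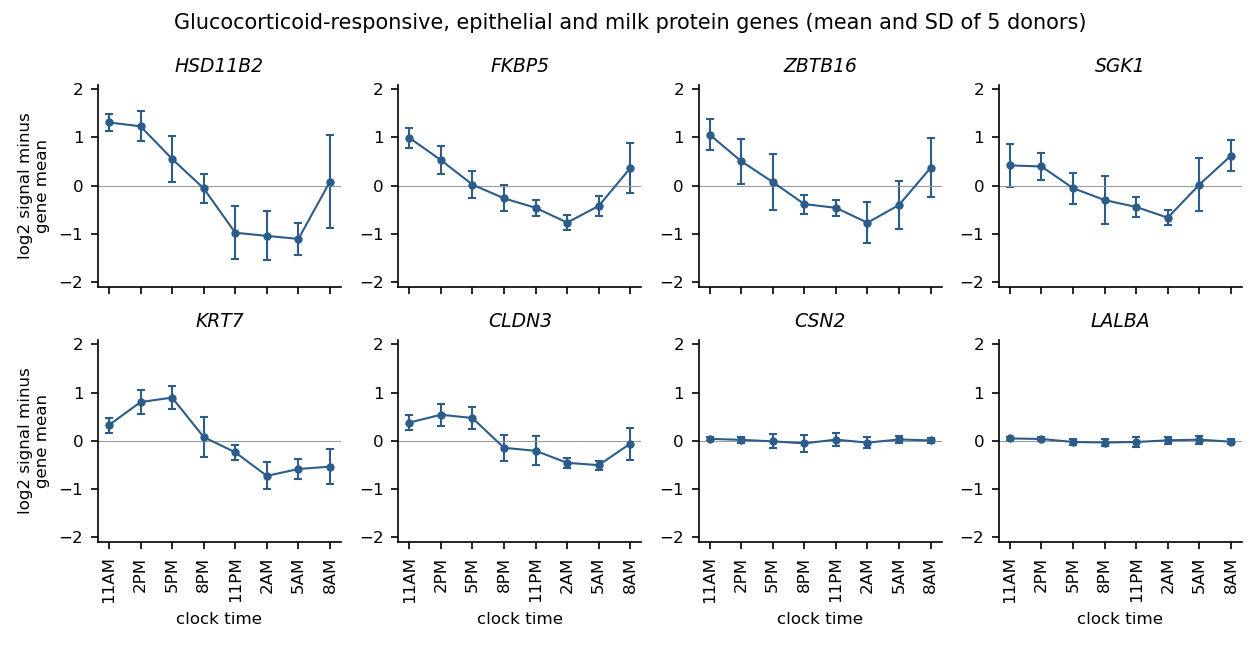
Log2 signal of genes outside the clock minus each gene's mean (vertical axis) against clock time (horizontal axis), with points for the mean of 5 donors joined by lines and bars for the SD of the donors after each donor's own mean was removed. HSD11B2 and KRT7 peaked in the afternoon (13.6 h and 15.5 h), while LALBA had a fitted amplitude of 0.03.

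Metabolic lists held rhythmic genes with different peak hours. GPAM, which encodes the first enzyme of triglyceride synthesis, peaked at 3.23 h (0.45 ± 0.06). ACACB peaked at 14.6 h (0.38 ± 0.05) and PDK4, an inhibitor of pyruvate dehydrogenase, at 13.7 h (0.53 ± 0.10). PDK4 was not called with a linear term for collection time (adjusted p = 0.091). GPAM, ACACB and PDK4 were among 12 of 30 rhythmic fatty acid and triglyceride genes (13 adjusted over the list alone). Cholesterol synthesis had 8 of 18 rhythmic (10 adjusted over the list alone), and lactose synthesis and glucose handling 10 of 22 (10). Mineral and amino acid transport had 10 of 22 (10), and prolactin, growth hormone and insulin signalling 5 of 18 (5), with PRLR at 3.06 h (0.14 ± 0.04). PRLR was not called without donor D, without 2PM, without 2AM, without the donor block or with the linear term (adjusted p = 0.073, 0.070, 0.081, 0.33 and 0.32). The proteasome list had 15 of 28 (19 adjusted over the list alone), and heat shock 10 of 22 (12). For endoplasmic reticulum and secretion it was 12 of 32 (14), for immediate early genes 7 of 17 (7) and for cell cycle 4 of 9 (4). Fisher's exact test called none of these shares (adjusted p from 0.063 to 1.0). Ribosomal protein genes were rhythmic less often than other genes, 4 of 60 (2 adjusted over the list alone, Fisher's exact test, adjusted p = 0.00017). So were oxidative phosphorylation genes, 11 of 72 (5 adjusted over the list alone, adjusted p = 0.017). Among markers of other cells 4 of 9 monocyte and macrophage, 2 of 3 neutrophil, 0 of 2 lymphocyte, 2 of 4 endothelial and 2 of 4 adipocyte genes were rhythmic. No fibroblast or red blood cell marker was kept.

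Over all probes the 24 h test called 3143 of 9967 (31.5%), for 2683 of 8568 genes. The called probes had a median amplitude of 0.20 and a median change from trough to peak of 1.31-fold. Of the 127 named genes 114 were called, 40 of them under every alternative, PER2, CRY2, CRY1, NR1D2, HSD11B2 and KRT7 included. Most named genes were chosen for a call, so the 114 of 127 follows largely from the naming rule. A change of at least 1.5-fold was fitted for 513 of the called probes and of at least 2-fold for 71. Peak hours fell into an afternoon and a night group. There were 614 genes from 12 to 15 h, 480 from 15 to 18 h, 474 from 0 to 3 h and 503 from 3 to 6 h, against 127 to 200 in any other 3 h window from 6 h to 12 h or from 18 h to 24 h. Any difference among the 8 clock times was called for 1206 probes, 1157 of them also rhythmic. The 24 h count was 1932, 1947 and 1725 without donor A, D or E, 2034 without 2PM, 593 without the donor block, and 639 with a linear term for collection time in the fit. The count for any difference among clock times was 406, 695, 499 and 604 without donor A, C, D or E, 703 without 11AM, 765 without 2PM, 51 without the donor block and 3455 with array weights.

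**Figure D3:**
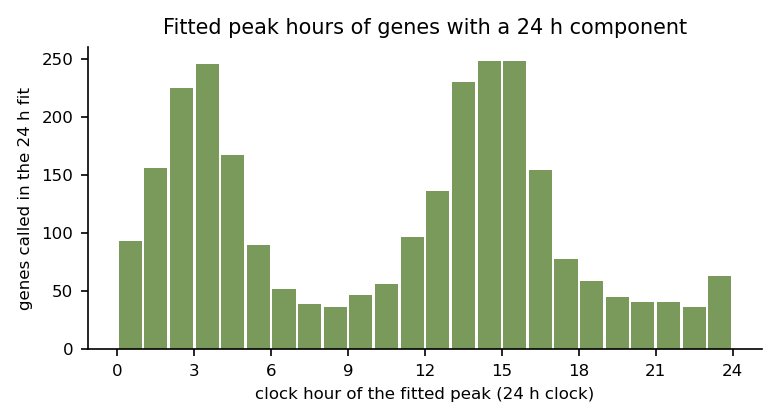
Number of genes with a called 24 h rhythm (vertical axis) by the hour of their fitted peak (horizontal axis, 24 h clock, 1 h bars). The bars are highest at 14 and 15 h, with 248 genes each, and at 3 h, with 246.

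The night against day contrast asked what differed between the samples of 11PM to 5AM and those of 11AM to 5PM. In both contrasts the adjusted p-values come from the fit's error over all arrays, not from the donor SD beside them. At night HSD11B2 fell by 2.08 ± 0.64 (SD, n = 5 donors, adjusted p = 3.8e-10), but was above background on only 5 of 15 night and 15 of 15 day arrays. PER2 fell by 1.68 ± 0.23 (adjusted p = 1.2e-09) and CRY2 fell by 1.20 ± 0.20 (adjusted p = 1.2e-13), each in 5 of 5 donors. SLC1A3 fell by 1.41 ± 0.20, VTCN1 by 1.26 ± 0.30, TENT5B by 1.21 ± 0.34, and KRT7 by 1.19 ± 0.28. PPL, which encodes the desmosomal protein periplakin, fell by 1.15 ± 0.47, but was above background on only 2 of 15 night and 14 of 15 day arrays. TEF and the transcription factor gene TFCP2L1 were above background on 12 of 15 day arrays each and on no night array. They were at least 1.27-fold and at least 1.29-fold lower at night (adjusted p = 6.8e-10 and 7.2e-11).

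Other genes were higher at night. The actin gene ACTG1 was higher by 1.11 ± 0.52 (SD, n = 5 donors, adjusted p = 0.00014), the tubulin gene TUBA1A by 0.90 ± 0.53. CDK5R1, an activator of the kinase CDK5, was higher by 0.97 ± 0.17 (adjusted p = 1.9e-10), the microtubule-binding gene DCX by 0.80 ± 0.51 and BANF1, whose product binds chromatin at the nuclear envelope, by 0.81 ± 0.36. HIF1A, the oxygen-regulated transcription factor, was higher by 0.87 ± 0.42 (adjusted p = 0.00041), the peroxisomal gene PXMP4 by 0.85 ± 0.71 (0.41 ± 0.19 by another probe) and the cytokine gene IL33 by 0.75 ± 0.27. LTF was higher by 0.49 ± 0.37 (adjusted p = 0.0048) in 5 of 5 donors.

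The proteasome and ubiquitin list had 14 of 28 genes higher at night and none lower (15 adjusted over the list alone, median 0.16, adjusted p = 2.6e-05). With an estimated correlation its adjusted p = 0.14. PSMC4, an ATPase of the proteasome cap, was higher by 0.78 ± 0.50, PSMD6 by 0.45 ± 0.44 and PSMD14 by 0.41 ± 0.20. Cholesterol synthesis had 7 of 18 higher and none lower (7 adjusted over the list alone, median 0.19, adjusted p = 0.0028, and adjusted p = 0.46 with an estimated correlation). MVD was higher by 0.72 ± 0.47, SQLE by 0.64 ± 0.34 and ACAT2 by 0.57 ± 0.26. Heat shock and cytosolic chaperones had 8 of 22 higher and none lower (9 adjusted over the list alone, median 0.12, adjusted p = 0.024, and adjusted p = 0.46 with an estimated correlation). HSPD1 was higher by 0.43 ± 0.34. HSF1 was higher by 0.59 ± 0.33, but was above background on only 7 of 15 day and 13 of 15 night arrays. The heat shock call was lost with 75th percentile scaling (adjusted p = 0.094) and without donor A (adjusted p = 0.16).

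In the glucocorticoid responsive list 12 of 16 genes were lower at night (13 called adjusted over the list alone, median −0.41, adjusted p = 1.8e-05, and adjusted p = 0.19 with an estimated correlation). Among them were FKBP5 at −1.07 ± 0.33 and ZBTB16 at −1.09 ± 0.59. ZBTB16 was above background on 5 of 15 night and 14 of 15 day arrays. The single gene of that list that was higher, at 0.31 ± 0.23, was NR3C1, the glucocorticoid receptor itself, named after its values were seen. The circadian clock list had 8 of 16 lower and only NPAS2 higher, at 0.52 ± 0.17 (11 called adjusted over the list alone, median −0.17, adjusted p = 0.0012). It kept its call with an estimated correlation (adjusted p = 0.016). Mineral and amino acid transport had 9 of 22 lower and none higher (9 adjusted over the list alone, median −0.15, adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation). They included the calcium pump gene ATP2B2 at −0.81 ± 0.32, the metal ion transporter gene SLC11A2 at −0.65 ± 0.34 and the amino acid transporter genes SLC1A1 at −0.58 ± 0.13 and SLC38A2 at −0.51 ± 0.10.

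Luminal epithelial markers were lower at night for 6 of 16 genes and higher for none (6 adjusted over the list alone, median −0.15, adjusted p = 0.020, and adjusted p = 0.23 with an estimated correlation). CLDN3 was at −0.85 ± 0.18. The luminal call was lost with the mean over a gene's probes (adjusted p = 0.060). All 5 tested myoepithelial and basal markers were lower (5 adjusted over the list alone, median −0.37, adjusted p = 0.0025, and adjusted p = 0.026 with an estimated correlation). They were the integrin gene ITGB4 at −0.69 ± 0.44, and the contractile genes TAGLN at −0.37 ± 0.12 and ACTA2 at −0.25 ± 0.10. The others were, named after their values were seen, VIM at −0.74 ± 0.54 and CALD1 at −0.20 ± 0.09. TAGLN was above background on 10 of 15 night and 14 of 15 day arrays, and ACTA2 on 12 of 15 and 15 of 15. Of the 12 basal markers with a probe, 7 were detected on no array and only 1 on all 40. Immune cell markers went both ways. Monocyte and macrophage markers had 3 of 9 higher and 2 lower (8 called adjusted over the list alone, median −0.32, adjusted p = 0.63), with MRC1 at 0.55 ± 0.45 and CD14 at −0.33 ± 0.11. MRC1 was above background on only 9 of 15 night and 9 of 15 day arrays. Of 3 neutrophil markers S100A8 was lower at −0.85 ± 0.73 (2 called adjusted over the list alone, median −0.36, adjusted p = 0.39).

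The remaining lists were not called as a whole by camera, and the parentheses open with the number of genes called when adjusted over the list alone. Milk protein and fat globule membrane genes had 3 of 25 higher and 7 lower at night (11, median −0.03, adjusted p = 0.14, but 0.0013 by fry). Fatty acid and triglyceride genes had 8 of 30 higher and 4 lower (12, adjusted p = 0.62), with GPAM at 0.67 ± 0.23 and ACACB at −0.59 ± 0.28, a median of −0.02 and a mean of 0.02. Lactose and glucose genes had 4 of 22 each way (9, adjusted p = 0.89), with a median of −0.03 and a mean of 0.02. Prolactin, growth hormone and insulin genes had 2 of 18 higher and 3 lower (5, adjusted p = 0.85), with the insulin receptor substrate gene IRS1 at 0.43 ± 0.25 and CCND1 at −0.40 ± 0.38. Immediate early genes had 1 of 17 higher and 2 lower (3, adjusted p = 0.79), and endoplasmic reticulum and secretion 5 of 32 higher and 3 lower (7, adjusted p = 0.55). Cell cycle had 3 of 9 lower (3, adjusted p = 0.081, but 6.7e-05 by fry), with CDC20 at −0.81 ± 0.17. Ribosomal proteins had 4 of 60 higher and 1 lower (0, adjusted p = 0.39) and oxidative phosphorylation 7 of 72 higher and 1 lower (6, adjusted p = 0.063). Endothelial markers (PECAM1 at 0.45 ± 0.23, VWF at −0.34 ± 0.50) and adipocyte markers (LIPE at 0.40 ± 0.33, FABP4 at −0.65 ± 0.69) had 1 of 4 each way (2 and 2, adjusted p = 0.73 and 0.76). VWF was above background on only 3 of 15 night and 7 of 15 day arrays, and FABP4 on 8 of 15 and 9 of 15. For VWF 1 donor was at −1.23 and the others were from −0.21 to −0.07. Of the 2 lymphocyte markers none was called.

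**Figure D4:**
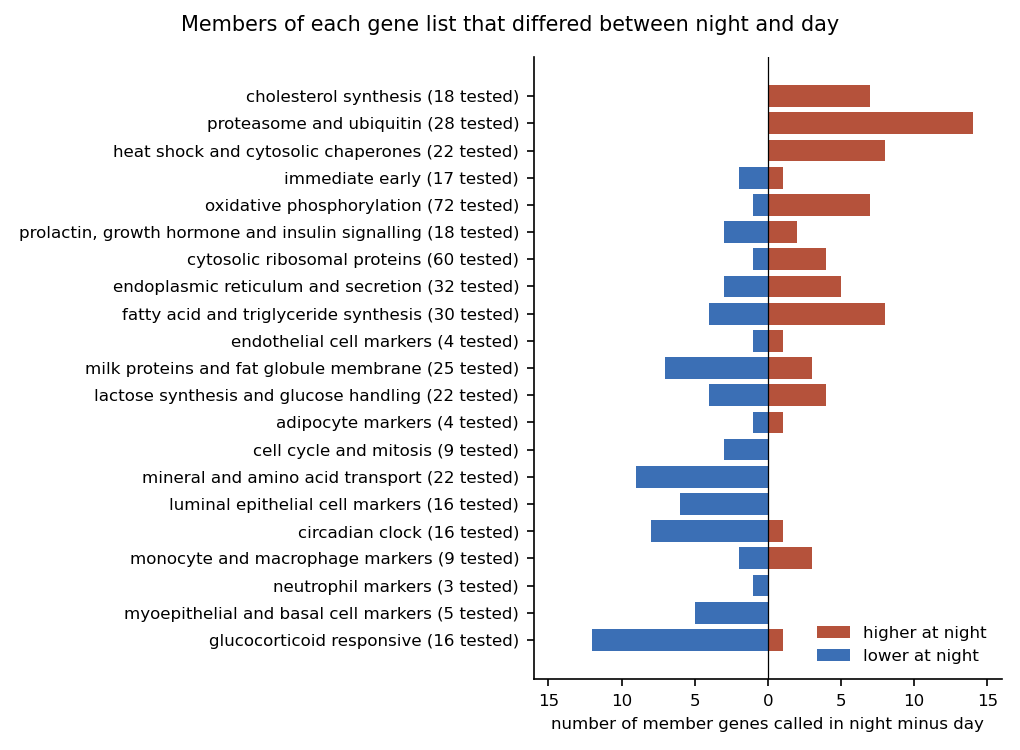
Number of genes called in night minus day (horizontal axis) for each list with at least 3 tested genes (vertical axis), higher at night to the right and lower to the left. Proteasome and ubiquitin genes lie to the right, with 14 higher and none lower, and glucocorticoid responsive genes to the left, with 12 lower and 1 higher.

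In all 2863 probes differed between night and day, 1417 higher and 1446 lower at night, and 2456 of them were also rhythmic. Scaled to the 75th percentile, which moved the median of all probes by 0.05, the split was 1962 higher and 1050 lower. By gene 1099 were higher and 1328 lower, and of 2421 genes open to naming 1606 had the same sign in all 5 donors. The count was 1822 and 1625 without donor A or E, 1886 without 2PM, 1773 without 5AM and 642 without the donor block. The sample numbers in the labels run from 11AM to 8AM. If they give the order of collection, which the labels do not state, night samples were also collected 12 h later than day samples.

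The evening against morning contrast asked what differed between 5PM to 11PM and 5AM to 11AM. NR1D2 was above background on 13 of 15 morning arrays and on no evening array. It was at least 1.54-fold lower in the evening (adjusted p = 8.8e-13). TEF fell by 0.72 ± 0.24 (SD, n = 5 donors, adjusted p = 6.0e-05) but was above background on only 4 of 15 evening and 10 of 15 morning arrays. SGK1 fell by 0.62 ± 0.41. ZBTB16 fell by 0.60 ± 0.55, above background on 9 of 15 evening and 12 of 15 morning arrays. CRY1 was higher by 0.77 ± 0.36 (adjusted p = 3.5e-05), and PROM1, a membrane protein gene of epithelial protrusions, by 0.78 ± 0.22. So were ALOX5, the lipoxygenase of leukotriene synthesis, by 0.77 ± 0.27 (adjusted p = 1.9e-06), and ASS1, an enzyme of arginine synthesis, by 0.61 ± 0.12. Each of these had the same sign in 5 of 5 donors. For PROM1, ALOX5 and ASS1, named only through this contrast, the naming rule required that sign, so it adds no support.

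The endoplasmic reticulum and secretion list had 6 of 32 genes higher in the evening and none lower (8 adjusted over the list alone, median 0.10, adjusted p = 0.00010, and adjusted p = 0.30 with an estimated correlation). HSPA5, the main chaperone of that compartment, was higher by 0.69 ± 0.53 (adjusted p = 0.0011), MANF by 0.68 ± 0.47, HYOU1 by 0.43 ± 0.46 and SDF2L1 by 0.40 ± 0.20. RRBP1, a ribosome-binding protein gene of the same membrane, was higher by 0.74 ± 0.45. Glucocorticoid responsive genes were lower in the evening for 7 of 16 and higher for none (7 adjusted over the list alone, median −0.24, adjusted p = 3.0e-05, and adjusted p = 0.23 with an estimated correlation). Proteasome genes were lower for 2 of 28 (2 adjusted over the list alone, median −0.08, adjusted p = 0.0062, and adjusted p = 0.30 with an estimated correlation), with PSMD14 at −0.23 ± 0.15. Their call was lost without donor B (adjusted p = 0.056).

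Shifts were called for 4 more lists and none held with an estimated correlation. Heat shock genes had 2 of 22 higher, HSPA1A at 0.50 ± 0.26 and HSPA1B at 0.45 ± 0.23, near-identical genes that probes do not separate reliably. Their list had 2 called when adjusted over the list alone (median 0.07, adjusted p = 0.024, and adjusted p = 0.46 with an estimated correlation). Immediate early genes had 1 of 17 each way (5 adjusted over the list alone, median 0.14, adjusted p = 0.024, and adjusted p = 0.46 with an estimated correlation). GADD45A was the lower one, at −0.45 ± 0.33, and ATF3, named after its values were seen, the higher one, at 0.42 ± 0.35. Luminal epithelial markers had 2 of 16 higher, KRT7 at 0.51 ± 0.23 and, named after its values were seen, KRT18 at 0.34 ± 0.23 (4 adjusted over the list alone, median 0.08, adjusted p = 0.049, and adjusted p = 0.30 with an estimated correlation). Oxidative phosphorylation had none called (0 adjusted over the list alone, median −0.04, adjusted p = 0.037, and adjusted p = 0.52 with an estimated correlation). Scaled to the 75th percentile, the heat shock, immediate early and luminal lists lost their calls (adjusted p = 0.16, 0.053 and 0.17), and ribosomal proteins gained one (median −0.08, adjusted p = 2.8e-05). All 4 lists lost their calls without donor D (adjusted p from 0.063 to 0.51). The call of oxidative phosphorylation also ended without donor B (0.15), of heat shock without B or C (0.075 and 0.31), of immediate early genes without C (0.067) and of luminal markers without A or E (0.10 and 0.084). Heat shock and immediate early genes lost theirs without the array with the fewest probes detected (0.077 and 0.056). Without the donor block immediate early genes and luminal markers lost theirs (0.065 and 0.059), and luminal markers also without background correction (0.058) and with the mean over probes (0.063).

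The other lists were not called by camera between evening and morning, with adjusted p = 0.89 for milk proteins, 0.998 for fatty acid and triglyceride synthesis, 0.79 for cholesterol, 0.58 for lactose and glucose and 0.51 for the circadian clock (0.016 by fry). The adjusted p was 0.39 for prolactin, growth hormone and insulin, 0.96 for transport, 0.39 for cell cycle, 0.89 for basal, 0.53 for monocyte and macrophage, 0.063 for neutrophil, 0.89 for endothelial, 0.39 for adipocyte and 0.090 for ribosomal protein genes. In the clock list 2 genes were higher and 3 lower (9 called adjusted over the list alone), with a median of 0.0029 and a mean of −0.07. In all 403 probes differed, 195 higher and 208 lower in the evening. By gene 181 were higher and 185 lower, and 319 of 366 had the same sign in all 5 donors. The count was 169, 158, 88 and 250 without donor A, C, D or E, 34 without 8AM, 211 without 5PM, 245 without 8PM, 8 without the donor block and 997 with array weights.

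The last comparisons asked how far donors differed in level and in rhythm. Donor level differed for 8423 probes (84.5%). The files do not say which arrays shared a chip, so this count and the donor share below may include differences between chips. Over the kept probes, donor took a median of 45.5% of a probe's variance, clock time 13.7% and the residual 37.1%. These shares were not corrected for the number of donors and clock times compared, so noise alone gives each a part of its share. The 13.7% therefore does not measure the effect of time of day, and the part due to noise was not estimated. The 24 h rhythm itself differed between donors for 11 probes, against 1645 (16.5%) at an unadjusted p under 0.05. That count was 7, 2, 1, 0 and 30 without donor A, B, C, D or E, 190 without 5PM and 1 to 3 without any other clock time. It was 20 with 75th percentile scaling, 7 without the filter, 114 with array weights and 25 without the array with the fewest probes detected. Among named genes the peak hours of PER2, CRY2 and SLC1A3 had standard errors of 0.34, 0.24 and 0.30 h. These come from the scatter of all arrays around a common curve and do not measure how far donors' peak hours differed. CRY2, PER2 and HSD11B2 were lower at night in 5 of 5 donors.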

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

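The tests of a steady drift and of array quality were chosen after the results were seen, and the regroupings of the arrays before.

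For 11 contrasts of named genes 1 of the 5 donors lay far from the others, as measured by the gap to the nearest donor divided by the whole range. The critical value was 0.71, and 11 of the 262 groups tested (4.20%) exceeded it, where chance exceeds it in about 1 group in 20. For night minus day the ratio was 0.762 for CD68, 0.753 for LIPE, 0.718 for PPL, 0.75 for SLC1A1, 0.757 for STAT5A, 0.794 for TENT5B and 0.88 for VWF. For evening minus morning it was 0.716 for ACTA2, 0.72 for CDK2AP2, 0.774 for HLF and 0.736 for KRT7. PPL, TENT5B, SLC1A1, CD68, LIPE and VWF had the same sign in all 5 donors in night minus day, and CDK2AP2 and KRT7 in evening minus morning. For CDK2AP2 the naming rule required it. VWF and PPL were above background on only 3 and 2 of 15 night arrays.

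The 24 h rhythm differed between donors for 11 probes in a test of the interaction. Of 100 regroupings, the real one included, 1 gave as many, and the highest other count was 9. The margin over chance was thus small. The number of calls moved between 0 and 30 when 1 donor was left out, and no explanation was tested.

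The count of probes with differences over the day was far above what regroupings gave. With clock times permuted within donors, 1 of 100 regroupings, the real one, reached the 3143 calls of the 24 h test (highest other 1). It was also 1 of 100 for the 1206 calls among clock times (highest other 2) and for the 2863 calls of night minus day (highest other 18). A share of 1 in 100 is the lowest that this number of regroupings can give. Random orders of a donor's clock times thus did not reach these counts. The regroupings also break any likeness between neighbouring samples of a donor. They therefore cannot tell a 24 h rhythm from another smooth course within donors. For the 403 calls of evening minus morning it was 2 of 100, since 1 other regrouping gave 415 and the next highest 0. Chance can thus give as many calls, though it rarely did. The real count also fell to 34 without 8AM and 88 without donor D. The cause of the 415 was not tested. Donor differences, with donors permuted within clock times, reached 8423 in 1 of 100, with 830 as the highest other.

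The many differences between night and day were weighed against a steady drift and against array quality. The order of collection, on which the drift tests rest, was read from the sample numbers, since the labels do not state it. Under a steady drift, the 8AM samples would lie 1.75 times as far from those of 11AM as night from day (21 h against 12 h). Over the called probes the slope was 0.717 (0.649 to 0.770 without any 1 donor), far from 1.75 but above the 0.453 of the fitted 24 h curves, and 8AM and 11AM ranked 11 of 28 among pairs of clock times by distance. A linear term in the 24 h fit shared 65.0% of its variance with the 24 h terms, took the median amplitude of the called probes from 0.20 to 0.17 and its SE from 0.05 to 0.07, and left 623 of the 3143 called. The loss came with a larger error as well as a smaller amplitude, and the linear term itself was called for 10 probes, with 880 at an unadjusted p under 0.05. Without the 24 h terms it was called for 2337. A steady drift as the whole cause can thus be excluded, but not as a part. With the number of probes detected as a covariate, 89.6% of the called probes (2564 of 2863) kept their call. The number of probes detected did not differ detectably among clock times (permutation test within donors, p = 0.72), so this covariate could remove few calls. The result does not bear on other measures of array or RNA quality. A slower process that returns within the day, such as milk volume or time since the last feed, stays open as untested.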

How the results depend on the processing

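The linear term for collection time, the covariate for probes detected and the fits without the array with the fewest probes detected were chosen after the data were seen.

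No background correction, the authors' processed values, the trended and robust prior, the filter on all 40 arrays, a random donor effect and the covariate for probes detected left every count tried under them within 1.5 times its value, as did the 12 h harmonic for the 24 h test (3147). Without the donor block, which removes the pairing of a donor's arrays, calls fell to 593 for the 24 h test, 51 for any difference among clock times, 642 for night minus day and 8 for evening minus morning, since differences between donors then enter the residual. With array weights, any difference among clock times gave 3455, evening minus morning 997 and the difference between donors in rhythm 114, and the cause was not tested. That last count was 20 with 75th percentile scaling, 7 without the filter and 25 without the array with the fewest probes detected. The linear term left 639 calls in the 24 h test, with amplitudes less precise as the term shares variance with the 24 h terms.

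Without any 1 donor, the count was 1725 to 3221 for the 24 h test, 406 to 1223 for any difference among clock times, 1625 to 3029 for night minus day, 88 to 594 for evening minus morning, 7538 to 7971 for donors, 0 to 30 for donors' rhythms and 11 to 17 for lists, and the p for probes detected was 0.511 to 0.877. Without any 1 clock time, the counts were 2034 to 3069, 703 to 1347, 1773 to 2785, 34 to 583, 7839 to 8323 and 1 to 190 in the same order up to the donors' rhythms, the 34 without 8AM and the 190 without 5PM. Fewer arrays lower the power of each of these fits.

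Of the 42 tests of a list in a contrast, 15 were called by camera, 2 with an estimated correlation (circadian clock and basal markers at night), 15 by fry and 25 by fry in either direction, which asks another question. The lists called by fry were not all those of camera: it added milk proteins and cell cycle at night and the clock in the evening, and left out heat shock, immediate early and oxidative phosphorylation genes in the evening. No list median changed direction in an alternative where its list was called there or in the main fit. Directions of lists called in neither were not compared. Of all values, 430 stayed on the same side of the threshold, 9 were newly past it and 23 were no longer past it.

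Of 127 named genes, most of them chosen for a call, 114 were called in the 24 h test, 40 of them under every alternative. Over all alternatives, 2937 of their values stayed on the same side of the threshold, 329 were no longer past it and 1 was newly past it, CLOCK without 2AM (adjusted p = 0.029). With the linear term, among genes called with or without it, the fitted peak moved by more than 6 h for CD68 (amplitude 0.10) and RPS15 (amplitude 0.10). Neither was then called (adjusted p = 0.54 and 0.39), and the cause was not tested. Night against day split into 1417 higher and 1446 lower probes with quantile normalization and into 1962 and 1050 with 75th percentile scaling. At a detection threshold of 0.05, 426 list members in place of 386 were detected on all arrays, and the p for probes detected was 0.50.

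Signal over background limits the dim genes, since NR1D2, TEF, TFCP2L1, DBP, PPL, CLDN4 and VWF were at background on all 5 arrays of at least 1 clock time. A block for the physical chip was not run, because the files do not identify it.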

Other observations

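The tests of the brightest probes were chosen before the results were seen, and the test of leukocytes after.

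Some genes with a daily course belong to none of the groups described so far. ANPEP, which encodes the membrane aminopeptidase N, peaked at 16.2 h with an amplitude of 0.71 ± 0.06 (SE of the fit). RAB31, a vesicle transport gene, peaked at 14.8 h with 0.68 ± 0.08. The zinc transporter gene SLC39A12 peaked at 5.30 h with 0.48 ± 0.05 and was lower in the evening than in the morning by −0.58 ± 0.22 (SD, n = 5 donors), XRCC3, a DNA repair gene, by −0.57 ± 0.35, and the scavenger receptor gene COLEC12 by −0.58 ± 0.34. Also lower in the evening were UBE4A at −0.65 ± 0.19, PRIM2, a primase subunit gene, at −0.62 ± 0.41 and KCTD8 at −0.55 ± 0.26. CDK2AP2 and ZNF165 were higher in the evening at 0.67 ± 0.14 and 0.62 ± 0.22. All of these contrasts were called, with the same sign in 5 of 5 donors. The naming rule required both of genes taken from a contrast, so neither adds support. The 24 h call was lost in 4 of 26 alternatives for PRIM2 and in 1 each for UBE4A, COLEC12 and RAB31.

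Probes of 1 gene did not always share a course. The brighter ELF5 probe, for a transcription factor of the secretory epithelium, had an amplitude of 0.02 ± 0.03 (adjusted p = 0.81), while another ELF5 probe had 0.57 ± 0.10 with a peak at 2.56 h (adjusted p = 9.8e-05). SREBF1, the regulator of lipid synthesis genes, had a probe with 0.16 ± 0.05 at 15.7 h (adjusted p = 0.038), a call lost in 14 of 26 alternatives, and another, detected on 19 of 40 arrays, with 0.35 ± 0.09 at 0.70 h. Both HIF1A probes peaked at night, with amplitudes of 0.53 ± 0.10 and 0.46 ± 0.09. Which transcripts each probe reads was not tested.

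The 50 brightest probes, those of the caseins among them, hardly varied over the day, with a median amplitude of 0.04 against 0.11 for all kept probes. Of the 50, 5 were called. Scaled to the 75th percentile, without quantile normalization, their median amplitude was 0.0737, above the lower quartile of all kept probes (0.0729) and below their median (0.117). A hold of the brightest ranks by normalization was thus neither excluded nor shown. Their log2 signals followed the 75th percentile of the array with a median slope of 0.776 (0.730 to 0.839 without any 1 donor), against 1.02 for a set of less bright probes. That slope lies between the bounds set for compression near the top of the range and for its absence. A flat course of these transcripts in the cell, normalization and compressed signal therefore cannot be told apart for these probes, and the small amplitudes of CSN1S1, CSN2, CSN3 and LALBA may come from any of them.

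At night 6 of 16 luminal markers were lower (adjusted p = 0.020, 0.23 with an estimated correlation and 0.060 with the mean over probes). So were 5 of 5 tested basal markers, while 7 of the 12 with a probe were detected on no array. A larger share of leukocytes in the night samples was weighed as a cause. Leukocytes would raise all their markers, but of 14 tested leukocyte markers 3 were higher at night (MRC1, VSIG4 and LYZ) and 3 were lower by more than the SD between donors. These were CD14 at −0.33 ± 0.11, CD68 at −0.32 ± 0.16 and S100A8 at −0.85 ± 0.73. The rise of LYZ, 0.19 ± 0.22, did not exceed its SD. The markers thus did not rise together. A larger share of leukocytes was not excluded by 3 falling markers, of which S100A8 varied widely between donors. CD14 and LYZ also stand in the milk protein list, so the secreting cell may supply part of these values, and a rise of 1 kind of macrophage, for MRC1 and VSIG4, stays open. KRT8, another luminal marker, peaked at 21.3 h, apart from KRT7 at 15.5 h and CLDN3 at 14.3 h, but its call (adjusted p = 0.029) was lost in 9 of 26 alternatives and theirs in none. A different mix of epithelial cells or of their cytoplasm in the globules over the day was not tested.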
